A study of Arabidopsis thaliana with 12 samples.

How the data were processed

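The labels describe 12 samples of total RNA from Arabidopsis thaliana, 6 of the wild type and 6 of the atc6 mutant, numbered 1 to 6 in each genotype. Per the labels, both were grown on MS medium. The deposited values are intensities on a linear scale, in a table of 3439 probes by 12 samples. This unit was read from the values, which are never negative and reach at most 100. The scanner, the background correction and the scaling behind the deposited intensities are not given in the sources used here, and neither is the meaning of the top value, which 4 probes reached in 14 values. Median deposited intensities were 0.627, 0.623, 0.485, 0.489, 0.525 and 0.519 for wild-type replicates 1 to 6 and 4.46, 4.52, 0.500, 0.499, 0.323 and 0.323 for mutant replicates 1 to 6. The scale of mutant replicates 1 and 2 relative to the other samples stays unknown. Between 4.94% and 7.82% of the values of a sample were 0.

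The column medians and means differed by more than 5%, so the samples were quantile-normalized together, by a rule written before the data were examined. Probes at 0 in all samples (110) were left out, which left 3329. A pseudocount of 0.267, the 10th percentile of the positive normalized intensities, was added before log2, so that all differences are on the log2(value + pseudocount) scale and understate those of dim probes. No other filter on dim probes was applied. Quantile normalization sets all samples to a shared distribution, which removes any overall difference between genotypes.

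The labels do not say whether the 6 samples of a genotype are separate plants, separate arrays or repeated spots. By a rule also written before the data were examined, all 15 ways to divide 6 samples into 3 doublets were ranked by the correlation, across probes, of deviations from the genotype mean. The division into 1 and 2, 3 and 4, and 5 and 6 ranked first in both genotypes. Its correlations were 0.74, 0.67 and 0.64 in wild type and 0.89, 0.83 and 0.59 in the mutant, all above the required 0.3. The samples of a doublet were therefore treated as technical repeats and averaged on the log2 scale. Since nothing says that the doublets came from separate cultures, p-values measure only the spread between these samples, which may be technical.

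A check of whether the sample numbers pair the genotypes came from the data, since the labels do not say what a number marks. Deviations of samples with the same number correlated across probes at 0.11, 0.11, 0.19, 0.20, 0.30 and 0.26 for numbers 1 to 6. The highest with another number were 0.07, 0.07, 0.07, 0.04, 0.12 and 0.10. For the averaged doublets the same-numbered correlations were 0.07, 0.14 and 0.24, and the highest others 0.06, -0.02 and -0.05. Doublet 1 was thus hardly distinguishable from no pairing. At the level of samples every pair was above 0.1, so the numbers were taken to pair the samples, and the fit with a replicate block was run beside the fit without it. The main fit had been planned without a block, and p-values come from it unless a block is named.

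Differences between mutant and wild type were fitted with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, with Benjamini-Hochberg adjustment over 3329 probes and a threshold of 0.05. Gene lists with at least 4 measured genes were tested with camera at a preset inter-gene correlation of 0.01, and with an estimated correlation and fry beside it, adjusted over 10 lists. The photosynthesis genes were also averaged per doublet and tested with a two-sided exact permutation test, for which 3 against 3 values give no p under 0.1. The fit was tested on simulated data with the spread of these samples. Of 50 probes changed by each amount, 6% were recovered at 1.5-fold, 18% at 2-fold, 72% at 4-fold and 74% at 8-fold, and 4 of 3129 unchanged probes were called. All amounts were simulated at once, with noise independent between probes, and 89 probes were called. So many calls ease the adjusted threshold, so these shares overstate the recovery of a few changed probes. Of 2 simulated sets of 20 probes, camera called the raised one and not the unchanged one. All 20 probes of the raised set were changed 2-fold, while the lists tested here held 4 to 7 genes. This check therefore does not show what shift camera could detect in those lists.

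Genes were named from the platform's annotation, which can be old. It listed 1562 of the probes, 692 with a single gene and 870 with several, while 1877 probes were not listed and are unnamed here. Of the 692, 690 were matched by gene ID to the TAIR10.1 gene table, used for names only, and 2 were not. Probes with several genes or none are given by their number. A gene with several probes was represented by the brightest. Whether the annotation assigns each probe correctly was not tested.

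Before the data were examined, 18 gene lists of chloroplast functions with 311 genes were fixed, of which 15 genes in 8 lists had a probe of their own. The other 10 lists had no measured gene: the target and plastocyanin, thylakoid electron transport and ATP synthase, isoprenoid and carotenoid synthesis, proteases and chaperones, protein import, plastid transcription, starch metabolism, nitrogen and sulfur assimilation, jasmonate synthesis, and root plastid markers. They were not analysed here. For this reason 9 lists were added from the names of the single-gene probes, after the platform annotation was seen and before any difference was computed. The genes named in the text follow a rule fixed in advance: the target and plastocyanin genes, up to 12 passing probes per direction or otherwise the 5 with the smallest p, and up to 4 genes with the smallest p of each fixed list. For each added list up to 2 genes with the smallest p could be named, a rule chosen after the data were seen.

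Alternatives covered the normalization, the pseudocount, dim probes, the variance model, the replicate block, the averaging of doublets, single samples and doublets left out, the threshold, and the test. Those chosen after seeing the data were leaving out averaged doublets, leaving out replicates 1 and 2 of both genotypes, entering samples without averaging and without mutant replicates 1 and 2, a sample-number block, scaling to a common median before quantile normalization, and keeping probes at 0. Counting the fixed-list genes that pass when adjusted over all 15 of them was also chosen after seeing the data. Where samples were left out, the remaining ones were quantile-normalized again with a new pseudocount. Differences without a sample or doublet include the effect of that renewed normalization.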

Results

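RNA of Arabidopsis thaliana was measured on an array in 12 samples, 6 of the wild type (ecotype Columbia 0) and 6 of the mutant atc6, which lacks cytochrome c6. Cytochrome c6 is a haem protein of the chloroplast. The plants were grown on MS medium, a standard mineral medium for plant culture. The table gave 3439 probes per sample. Median deposited intensities of the 6 wild-type samples lay between 0.485 and 0.627. Those of mutant replicates 3 to 6 lay between 0.323 and 0.500, and mutant replicates 1 and 2 stood apart at 4.46 and 4.52. The samples numbered 1 and 2, 3 and 4, and 5 and 6 formed close doublets in both genotypes, so that each doublet was averaged and the comparison rested on 3 averaged doublets per genotype. That number limits the precision of every value. The knocked-out gene and both plastocyanin genes were not among the probes assigned to a single gene and were not analysed here, so the genotype of the samples could not be checked on the target transcript.

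**Figure D1:**
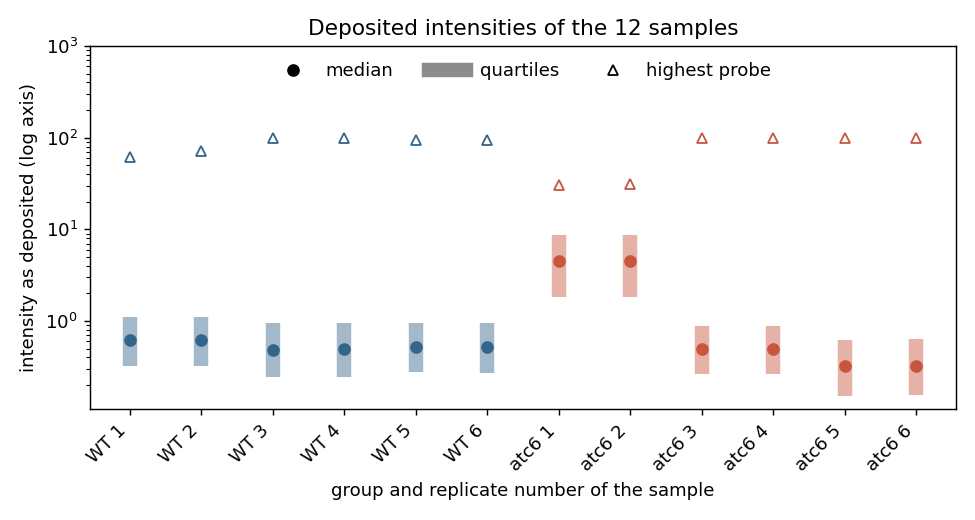
Intensities as deposited, on a log axis, for each of the 12 samples: points are medians over 3439 probes, bars span the quartiles and triangles mark the highest probe. Mutant replicates 1 and 2 have medians of 4.46 and 4.52 and highest values of 30.1 and 31.4, while the other 10 samples have medians between 0.323 and 0.627.

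The comparison of mutant and wild type asks which transcripts differ in plants without cytochrome c6. The gene with the smallest p among those with higher values in the mutant was PRK (AT1G32060, probe 3151), which encodes phosphoribulokinase, an enzyme of the Calvin-Benson cycle. The name of this probe rests on the platform's annotation alone. Its deposited intensities were 0.431 to 0.737 in wild type, around the sample medians, and 1.41 to 12.4 in the mutant, where replicates 1 and 2 are on another scale. The wild-type values are low for a transcript that is usually abundant in green tissue. Levels of different probes are not strictly comparable, so the assignment stays open. The log2 level of PRK was 0.55 ± 0.42 in wild type and 2.01 ± 0.37 in the mutant (SD, n = 3 averaged doublets each). This 2.74-fold difference was 1.46 ± 0.30 (SE), with a 95% interval of 0.76 to 2.16. Among the genes with lower values in the mutant it was AT4G31530 (probe 3215), with 4.71 ± 0.12 in wild type and 3.47 ± 0.07 in the mutant, a difference of -1.24 ± 0.21 (SE) with an interval of -1.72 to -0.76. For both genes the 3 normalized mutant values lay wholly on one side of the 3 wild-type values, which the choice by smallest p favours. As deposited, the values of AT4G31530 overlapped, at 18.0 to 26.7 in wild type and 9.19 to 21.1 in the mutant, again with replicates 1 and 2 on another scale. Neither gene passed limma's test over all 3329 probes fitted, with adjusted p = 0.785 for PRK and 0.436 for AT4G31530.

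No probe passed an adjusted p of 0.05 in limma (0 of 3329), with 167 probes (5.02%) at an unadjusted p under 0.05. An unmoderated test per probe on the same values also called 0, with 139 at an unadjusted p under 0.05. Mutant and wild-type values did not overlap for 372 probes (11.2%), 193 of them higher and 179 lower in the mutant. Chance gives 10% if all doublets are exchangeable, which ignores their pairing by number. The other 4 probes with the smallest p and higher values in the mutant were probes 3227, 4360, 4201 and 3426, none assigned to a single gene, with log2 differences of 1.09, 1.23, 0.98 and 0.76. Of the other 4 with lower values, likewise without a single gene, probe 1144 differed by -1.26. Its deposited values overlapped, at 0.672 to 0.837 in wild type and 0.22 to 1.11 in the mutant, where replicates 1 and 2 are on another scale. Probe 1802 had the smallest adjusted p of all, 0.0725. It was listed at 0 in all 6 mutant samples and at deposited intensities of 0.319 to 0.799 in wild type. Probe 1430 was at 0 in 5 mutant samples and probe 3502 in 3, against 0.114 to 0.412 and 0.208 to 0.634 in wild type. Probes 1802 and 1430 are numbered directly beside probes that are among the 20 brightest. In the other 26 probes numbered beside the 20 brightest, 28.8% of the mutant values and 14.1% of the wild-type values were at 0, against 6.14% and 5.52% in the remaining probes. The median 95% interval reached 0.67 on the log2 scale to either side. On data simulated with this spread, 18% of probes changed 2-fold and 72% of those changed 4-fold were recovered. With the spread that leaves out mutant replicates 1 and 2 it was 36% and 78%, still with 3 against 3 doublets. With that spread and 3 against 2 doublets, as when these replicates are left out, it was 14% and 72%. Many probes were changed at once in the simulation, which eases the adjusted threshold, so these shares overstate the recovery of a few changed probes. The count was 2 without mutant replicates 3 and 4 (330 at an unadjusted p under 0.05, against 66 without wild-type replicates 1 and 2), 1 without wild-type replicate 3, and 99 when all 12 samples were entered as if independent.

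The genes of the photosystems, their antennae and the thylakoid electron transport chain were the group closest to the design. Of these, 4 were measured by a probe of their own. PSBY, a small photosystem II subunit, had a log2 level of 1.87 ± 0.23 in wild type and 2.57 ± 0.26 in the mutant (SD, n = 3), a difference of 0.69 ± 0.24 (SE) with adjusted p = 0.845 in limma. PSAN, a lumenal subunit of photosystem I, differed by 0.10 ± 0.24 and LHCB1.5, a light-harvesting protein of photosystem II, by 0.07 ± 0.24. Without mutant replicates 1 and 2 these were 0.39 and 0.21. The difference of LHCB1.5 turned to -0.15 when samples were scaled to a common median. PSBW, another small photosystem II subunit, was at 1.35 in mutant replicates 1 and 2, against 5.49 and 4.66 in the other mutant doublets and 4.59 to 5.63 in wild type. None of the 4 passed over all probes.

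The mean log2 level of the 4 photosynthesis genes was 3.18 ± 0.20 in wild type and 3.10 ± 0.63 in the mutant (SD, n = 3), a difference of -0.08 with p = 1 in a two-sided exact permutation test, whose smallest possible p is 0.1. The mutant doublets were at 2.37, 3.51 and 3.42 and the wild-type doublets at 3.38, 2.97 and 3.20. Of the 4 genes, 3 had positive differences and only PSBW a negative one, at -1.18. The median over the genes was 0.08 and limma's camera placed the group above the other probes (p = 0.455, and p = 0.618 with an estimated correlation). The mean therefore differed in sign from the median and the test. Without mutant replicates 1 and 2 the difference turned to 0.41 (exact permutation p = 0.2), and without wild-type replicates 1 and 2 to 0.013. Leaving samples out also renormalized the rest. Without mutant replicates 1 and 2 the wild-type mean moved from 3.18 to 2.63, so the shift is not that of the doublet alone. With all samples the difference was 0.30 after cyclic loess, 0.01 after scaling to a common median and 0.72 on the values as deposited, where all probes shifted by a median of 0.66.

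**Figure D2:**
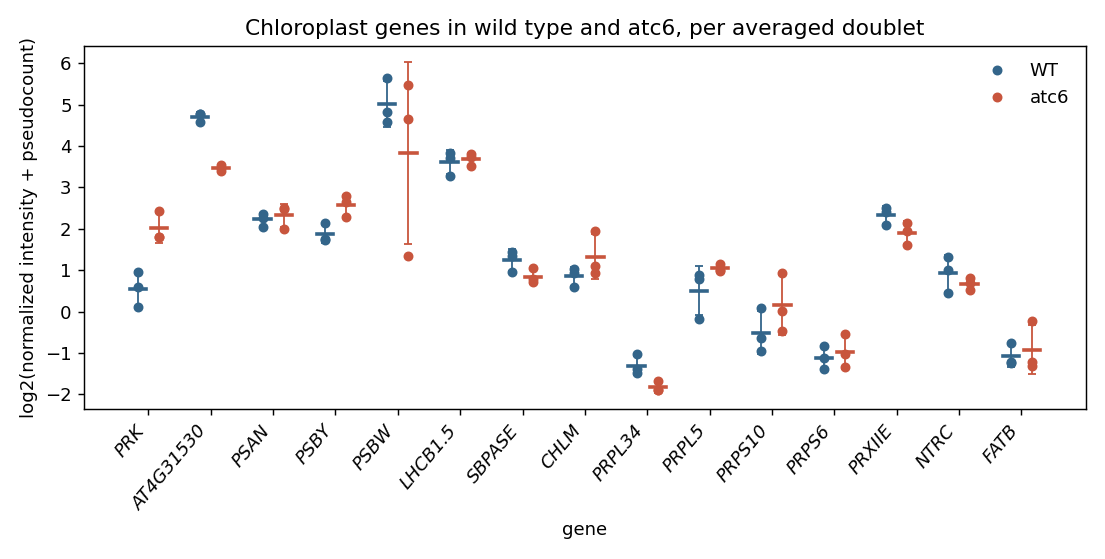
Log2(normalized intensity + pseudocount) of PRK, AT4G31530 and the named genes of the lists fixed in advance, one point per averaged doublet (3 per genotype), with the mean as a line and the SD as an error bar. PRK is higher and AT4G31530 lower in all 3 mutant doublets, and the spread of PSBW in the mutant comes from replicates 1 and 2, at 1.35.

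In the Calvin-Benson cycle list, 2 genes were measured. Beside PRK at 1.46, SBPASE, which encodes sedoheptulose-bisphosphatase, differed by -0.40 ± 0.24 (SE), and by -0.13 without mutant replicate 3 or -0.68 without mutant replicate 4. Across the 8 fixed lists with a measured gene, 15 genes were tested and 0 passed over all probes. Adjusted over the list alone, counting all 15 genes as a single list, 1 passed, PRK, with adjusted p = 0.0212 in limma. This count was chosen after the data were seen, so the pass is no independent support for PRK. The second-lowest adjusted p of the 15 was 0.163. Within single lists, again adjusted over the list alone, PRK passed in the Calvin-Benson list (adjusted p = 0.00283) and PSBY in the photosystem II list of 2 genes (adjusted p = 0.0434), and the other 6 lists gave 0. These p-values are not corrected across the lists, and PSBY did not pass over the 15 genes. The PRK call over the 15 genes was lost without wild-type replicates 1 and 2 (adjusted p = 0.106), wild-type replicates 3 and 4 (0.0976), mutant replicates 3 and 4 (0.0526) or mutant replicates 5 and 6 (0.113), and the difference stayed between 1.22 and 1.75 without any averaged doublet. It was also lost with scaling to a common median (adjusted p = 0.0504) and on the values as deposited (0.423), where the difference was larger, 1.65 and 2.36, and so was its SE, 0.38 and 0.86 against 0.30. With a common median set before quantile normalization PRK passed (adjusted p = 0.0185, difference 1.59).

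Plastid ribosomal proteins were the fixed list with most genes measured. Of its 5 genes, 4 had positive differences and 1 a negative one, and 0 passed, also when adjusted over the list alone. PRPL34 had 7 of its 12 deposited values at 0, so the size of its negative difference is set by the pseudocount, from -0.28 with the 25th percentile to -2.39 with the 1st. PRPL5 differed by 0.55 ± 0.32 (SE), PRPS10 by 0.66 ± 0.42 and PRPS6 by 0.14 ± 0.28. The mean over the list was 0.18 (camera adjusted p = 0.802, and adjusted p = 0.837 with an estimated correlation), and it turned to -0.13 with scaling to a common median and to -0.095 with the pseudocount at the 1st percentile. It was 0.018 without mutant replicates 5 and 6 and 0.067 without wild-type replicates 1 and 2. Without mutant replicates 5 and 6, PRPS10 was at 0.27, and without wild-type replicates 1 and 2, PRPL5 was at 0.21.

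The remaining fixed lists held 1 or 2 measured genes each and none passed. CHLM, a methyltransferase of chlorophyll synthesis, differed by 0.47 ± 0.31 (SE), and by 0.14 without mutant replicates 1 and 2. In the antioxidant list, the peroxiredoxin gene PRXIIE differed by -0.43 ± 0.25 and NTRC, which encodes a thioredoxin reductase with its own thioredoxin domain, by -0.26 ± 0.28. FATB, a thioesterase of fatty acid synthesis, differed by 0.14 ± 0.34 and turned to -0.06 after cyclic loess and to -0.36 with scaling to a common median. Without mutant replicates 1 and 2 PRXIIE was at -0.81 and FATB at 0.23. NTRC was at -0.063 without wild-type replicates 1 and 2 and at -0.51 without wild-type replicates 5 and 6.

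A further 9 lists were drawn from the gene names before any difference was computed, and 0 of their genes passed over all probes. In amino acid and sulfur metabolism, CBL, which encodes cystathionine beta-lyase, was at -0.01 ± 0.22 in wild type and 0.56 ± 0.12 in the mutant (SD, n = 3), and the cyanase gene CYN at 1.63 ± 0.18 and 0.57 ± 0.89. Their differences were 0.57 ± 0.22 (SE) and -1.05 ± 0.42, both with adjusted p = 0.845 in limma. CYN was at -0.44 in mutant replicates 1 and 2, and without them its difference was -0.60. In redox and photoprotection, NADP-MDH, the chloroplast malate dehydrogenase, differed by 0.84 ± 0.37. In the pigment pathway Z-ISO, an isomerase of carotenoid synthesis, differed by -0.85 ± 0.42, and by -0.34 without mutant replicates 1 and 2. NdhS, a subunit of the NDH complex, differed by -0.61 ± 0.42 and was at 1.77 in mutant replicates 1 and 2 against 3.39 and 3.22 in the other mutant doublets, and without these replicates its difference was -0.15.

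Means of the 9 lists lay between -0.16 for stress-responsive genes (4 of 5 genes negative) and 0.25 for photosystem and cytochrome complex assembly (4 of 4 positive). The flower and gamete regulators averaged 0.11 (6 of 7 positive), cell wall enzymes 0.10 (4 of 5), amino acid and sulfur metabolism 0.10 (3 of 4), redox and photoprotection 0.08 (3 of 7), the pigment pathway 0.05 (3 of 5), organelle RNA and DNA factors 0.01 (3 of 6) and the NDH complex -0.11 (1 of 5). Camera gave an adjusted p of at least 0.802 for all 10 lists tested, at least 0.837 with an estimated correlation, and fry at least 0.748. Mean and median differed in sign for redox and photoprotection (median -0.14), and the mean and the direction from camera for organelle RNA and DNA factors. Without mutant replicates 1 and 2, photosystem assembly turned to -0.18, organelle factors to -0.12, flower and gamete regulators to -0.05 and amino acid and sulfur metabolism to -0.01. In photosystem assembly PSB27, singled out after its value was seen, went from 0.41 to -0.82. The other genes of that list, CCB3, ATAB2 and LPA19, were then at 0.02, -0.01 and 0.09.

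**Figure D3:**
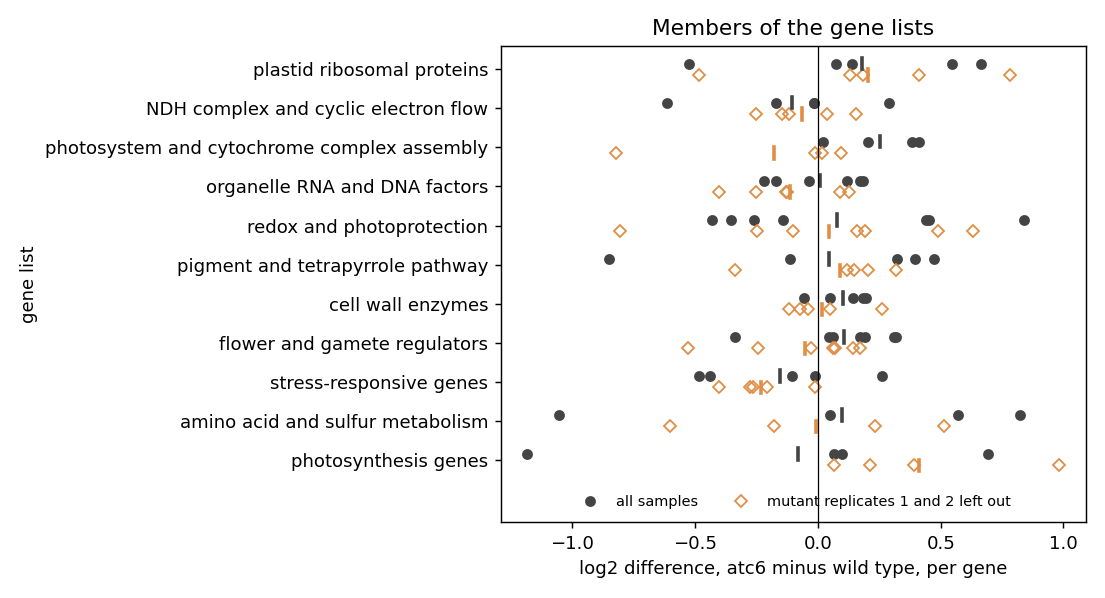
Log2 difference between atc6 and wild type for each gene of the 10 tested lists and of the photosynthesis group, with all samples (filled) and with mutant replicates 1 and 2 left out (open), and vertical lines at the list means. With all samples the list means lie between -0.16 and 0.25, and the mean of the photosynthesis genes moves from -0.08 to 0.41. For the open points the remaining samples were normalized again.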

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

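Tests and settings chosen only after the data were seen are leaving out averaged doublets, replicates 1 and 2 of both genotypes left out, the 6 against 4 samples, the sample-number block, scaling to a common median before quantile normalization, probes at 0 kept, and the count of fixed-list genes. The number of probes changed was 0 in most settings and 1 with the pseudocount at the 1st percentile, 1 with an intensity trend and robust prior and 1 with doublets as a random block, each time probe 1802. It was 0 to 2 with samples or doublets left out (2 without mutant replicates 3 and 4, the unnamed probes 3101 and 3102, singled out after their values were seen, and 1 without wild-type replicate 3, probe 1802). The large counts came from entering the samples of a doublet separately, which treats repeats as independent: 99 for 6 against 6, 55 for 6 against 6 with a replicate block by sample number, and 175 for 6 against 4 without mutant replicates 1 and 2. With the replicate block on averaged doublets the count was 0, PRK alone passed among the 15 fixed-list genes, and no list passed with camera. The permutation test of the photosynthesis genes takes no block, so its result could not change. The fixed-list genes passing, adjusted over these lists alone, numbered 1 and became 2 for 6 against 6, 2 with the sample-number block, 5 for 6 against 4, and 0 on the values as deposited, with median scaling, with probes at 0 kept and with replicates 1 and 2 of both genotypes left out. With samples or doublets left out they numbered 0 to 1.

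None of the 10 lists tested with camera passed the threshold under any alternative run. The photosynthesis genes, tested as a group, passed for 6 against 4 samples alone. Several differences changed sign, and the cause was not tested. On the values as deposited all probes shifted by a median of 0.66, and with it the photosynthesis genes (0.72), stress-responsive genes (0.49), the NDH complex (0.59), SBPASE (0.39), NTRC (0.48), PRXIIE (0.062), NdhS (0.16), XERICO (0.050), SIS (0.035), AGL103 (0.51) and mTERF9 (0.43) became positive. With median scaling the values were 0.011 for the photosynthesis genes, -0.13 for plastid ribosomal proteins, -0.21 for photosystem assembly, -0.12 for redox, -0.045 for the pigment pathway, -0.040 for amino acid and sulfur metabolism, -0.15 for LHCB1.5, -0.29 for PRPS6 and -0.36 for FATB. After cyclic loess they were 0.30 for the photosynthesis genes, -0.067 for amino acid and sulfur metabolism, -0.027 for the pigment pathway, -0.058 for redox, -0.0089 for organelle factors and -0.058 for FATB. Plastid ribosomal proteins were at -0.095 with the pseudocount at the 1st percentile, with which PRPL34 was at -2.39, probe 3227 at 1.83, SIS at -0.69, AGL54 at 0.47, GH9B8 at 0.35 and photosystem assembly at 0.40. With the pseudocount at the 25th percentile PRPL34 was at -0.28 and probe 3227 at 0.73. The pigment pathway was at -0.024 without the dimmest 25% of probes, and without the dimmer 50% organelle factors were at -0.076 and amino acid and sulfur metabolism at -0.11, on fewer genes.

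For 6 against 4 samples the photosynthesis genes were at 0.41 (exact permutation p = 0.0190, over samples that are not independent; 0.1 to 1 over the other alternatives), photosystem assembly at -0.18, organelle factors at -0.12, flower regulators at -0.051, amino acid and sulfur metabolism at -0.0089, PSBW at 0.066, ATAB2 at -0.011 and GH9B11 at -0.040. Without replicates 1 and 2 of both genotypes the photosynthesis genes were at 0.54, photosystem assembly at -0.15, organelle factors at -0.16, flower regulators at -0.039, PSBW at 0.42 and ATAB2 at -0.031. With single samples or doublets left out, the ranges that crossed 0 were -0.27 to 0.41 for the photosynthesis genes, -0.18 to 0.50 for photosystem assembly, -0.12 to 0.12 for organelle factors, -0.051 to 0.26 for flower regulators, -0.083 to 0.22 for amino acid and sulfur metabolism, -0.021 to 0.20 for cell wall enzymes and -0.038 to 0.12 for the pigment pathway. For single genes they were -1.91 to 0.066 for PSBW, -0.13 to 0.27 for LHCB1.5, -0.074 to 0.33 for PRPS6, -0.197 to 0.34 for FATB, -0.13 to 0.45 for GH9B11, -0.26 to 0.50 for GH9B8, -0.011 to 0.74 for ATAB2 and -0.40 to 0.049 for mTERF9. Other ranges moved by over 1.5 times without crossing 0: 0.018 to 0.28 for plastid ribosomal proteins, -0.18 to -0.039 for the NDH complex, 0.039 to 0.11 for redox, -0.23 to -0.031 for stress-responsive genes, 0.27 to 0.97 for PRPS10, 0.21 to 0.75 for PRPL5, -0.68 to -0.13 for SBPASE, -0.51 to -0.063 for NTRC, -0.81 to -0.27 for PRXIIE, 0.14 to 0.65 for CHLM, 0.0058 to 0.39 for PSAN, -1.18 to -0.34 for Z-ISO, -1.39 to -0.60 for CYN, -0.85 to -0.15 for NdhS, -0.67 to -0.21 for SIS, -0.53 to -0.11 for AGL103, 0.17 to 0.40 for AGL54 and 0.15 to 0.55 for CRR41. PRK and AT4G31530 kept their direction under all alternatives, which the choice by smallest p favours. So did others, among them PSBY, NADP-MDH, CBL, CYN, Z-ISO, CHLM and PSAN. Signal over background is not given in the sources used here, and values at 0 limit what the dimmest probes can show.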

Other observations

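Of the genes of the added lists that were not described above, none passed limma's test. XERICO, a gene of abscisic acid and drought responses, differed by -0.48 ± 0.30 (SE, n = 3 averaged doublets) between mutant and wild type, and SIS, named for its induction by salt, by -0.44 ± 0.27. The MADS-box genes AGL103 and AGL54 differed by -0.34 ± 0.30 and 0.31 ± 0.22. CRR41, needed for the assembly of the NDH complex, differed by 0.29 ± 0.29. The glycosyl hydrolase genes GH9B8 and GH9B11 differed by 0.20 ± 0.42 and 0.18 ± 0.35. The 3 mutant values of AGL54 lay above the 3 wild-type values. Without mutant replicates 1 and 2 the differences were -0.21 for SIS, -0.53 for AGL103, 0.17 for AGL54, 0.15 for CRR41, 0.05 for GH9B8 and -0.04 for GH9B11. Adjusted p values of these genes lay between 0.845 and 0.933.

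All tests in the following paragraphs were chosen after the result they bear on was seen. In all 10 splits of the 6 averaged doublets into 3 and 3, as in the real one, limma called 0 probes, so the highest of the other splits was 0 as well, and 10 splits are too few for a share under 0.05. At an unadjusted p under 0.05 the real split had 167 probes and the other splits 53 to 214. Among the 4 splits that part all 3 same-numbered pairs, the real one included, the other 3 had 79, 166 and 53.

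Mutant replicates 1 and 2 stood apart from the other 10 samples in scale and in the order of their probes. A different scale or a monotone compression of the intensities keeps ranks, yet the highest rank correlation of either sample with any of the other 10 was 0.740, below the lowest among those 10 (0.768, partners left out), while the pair itself agreed at 0.982, so this is argued against as the whole cause. A property of the filter shared with wild-type replicates 1 and 2, if the number marks a filter, was weighed by the correlation of deviations, 0.0679. The other same-numbered doublets reached only 0.14 and 0.24, so a low value cannot decide and this stays open. Signal unrelated to the RNA stays open. Relative to the spread of the other mutant doublets, the deviation was 0.514 times as large in the dimmest 25% of probes as in the brightest 25%. Its signed median went from 0.22 in the dimmest to -0.12 in the brightest, as added signal could give. Low rank agreement from any cause could give the same once samples share a distribution, so the sign cannot decide. A different RNA, different plants or a mislabelled sample stay open as well, and the design has no group that would test a biological explanation.

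The samples of a doublet differed from each other in the same way in both genotypes. The odd-minus-even difference of wild-type and mutant doublets with the same number correlated across probes at 0.60, 0.61 and 0.46, the lowest being 0.456, against at most 0.278 between doublets of different numbers. A candidate explanation is that an array was used for both genotypes and that the samples of a doublet are its repeated spots, so that 6 samples per genotype hold 3 measurements. The labels do not say so, and a shared scan or image grid per number would give the same.

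Probes 1802 and 1430, among the 5 lower probes with the smallest p, are numbered next to probes that rank among the 20 brightest. A hypothesis is that a bright spot lowers the value of a dim neighbour, for example through local background, and more so in the mutant samples. The other 25 fitted neighbours of the 20 brightest probes had a mean log2 difference of -0.626, with 21 negative. This lay below all of 10000 random lists of 25 probes, but its size was largest in mutant replicates 1 and 2. There the mean was -1.39 and the brightest probes themselves were at -1.46, so it cannot be told apart from a fall of both. In replicates 5 and 6 it was -0.41, where the brightest probes were at 0.01, which may be such an effect. In replicates 3 and 4 it was -0.08, within the random lists (percentile 10.8). Of the values of the 26 neighbours other than probes 1802 and 1430, 23.1% were at 0 in these mutant replicates 3 and 4. It was 17.3% in wild-type replicates 3 and 4 and 5.71% in other probes of the same mutant samples. Whether probe numbers follow positions on the array is not given in the sources used here, and lower transcript levels of these genes stay open as untested.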
